A study of Homo sapiens with 3 samples.

How the data were processed

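RNA from the MDA-MB-231 line, grown in DMEM with serum, was measured by SYBR green RT-qPCR. Per the labels' protocols, total RNA was isolated with TRI-Reagent, 2 µg was reverse transcribed per reaction, PCR ran for 40 cycles in GoTaq Green master mix on a realplex cycler, and each reaction had a melting curve. Primers were designed on the coding sequences, per the labels' protocols. Their positions, the software that called the Ct and any genome build are not given in the sources used here, so no coordinates are printed. The authors deposited a table of Ct values in cycles and a table of percentages of ACTB. No Ct is listed (ND) for some transcripts. Set against the Ct table, the deposited percentages of 492 target values equal 100 times 2 to the power of 15.21 minus the Ct, within 0.001 cycle. The ACTB entries use 15.1 instead, a 1.08-fold difference in reference. The same reference was used for all 3 repeats, so the deposited percentages carry no correction for differences in ACTB between repeats. The labels number the repeats, and the columns carry letters that the labels do not tie to those numbers, so the letters are kept and no repeat is paired with a label.

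From the Ct values, the level of each transcript was computed as the ACTB Ct minus the transcript Ct of the same repeat, with an amplification factor of 2 per cycle, then averaged on the log2 scale over the 3 repeats. A transcript was detected when its Ct was below 40 in all 3 repeats. PCR gives no read counts, so no sequencing depth applies, and precision is set by the 3 repeats and by how late the Ct is. Repeats were compared first and differ by a median of 0.31 to 0.59 cycles between columns, with 1 to 5 identical values, so none was counted as a duplicate. Of 179 symbols in the file, 174 are current in the RefSeq gene table (GRCh38.p14, used for names only), 3 matched a synonym and 2 did not match (NOTCH and NOV). Each transcript was classed as ligand, receptor or other from its gene name.

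Each ligand-receptor pair was tested with limma 3.58.1 in R 4.3.3 (intercept-only fit of the within-repeat log2 difference, empirical Bayes variance, Benjamini-Hochberg over 59 pairs, threshold 0.05). Pairs with an undetected member were given a bound at 40 cycles, which takes a missing Ct as no signal by the end of the run. Ligands were compared with receptors by a two-sided permutation test of medians (100000 resamples). Gene lists were described by their median and its percentile among 10000 random lists of detected transcripts, for lists of at least 3. Data were simulated for 59 pairs with the observed SDs, separate members and independent errors. In 50 runs limma called 2.53% of pairs with no true difference, 38.8% with a difference of 1 cycle, 72.4% with 2 and 92.7% with 4. The real pairs share members, so these rates need not hold for them. The permutation test, simulated on 162 transcripts in 100 runs, called 4.0% with no difference and 86.0% with 2 cycles. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

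The lists, the pairs, the tests, the alternatives and the rule for named transcripts were fixed before the data were examined. The rule takes the 12 highest and 8 lowest detected transcripts, the 5 with the largest SD, both members of the 10 pairs with the largest difference past the threshold and the undetected transcripts that belong to a fixed list. Other transcripts named, including list extremes, further pairs and the undetected FLT3, GH2, PRL and WNT3, were chosen after their values were seen. Alternatives were Ct limits of 35 and 30, detection in at least 1 repeat, another reference, the deposited percentages, an amplification factor of 1.9, undetected members at 40 cycles, a test against a 10-fold difference, no variance moderation, members as independent samples, means for medians, and leaving out each repeat. Others, chosen after seeing the data, left out values of exactly 35 cycles or rows of doubtful identity, added 39 textbook pairs (also leaving out each repeat), left out each repeat for the bounds, or kept 1 pair per ligand and receptor. The last took pairs in their listed order and dropped any that shared a member with a pair already kept. The rows of doubtful identity left out were those of CXCL11, IL2R and PROK1, while CXCL10, IL2 and PRKAR1A stayed.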

Results

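The data are cycle thresholds (Ct) from an RT-qPCR array of cytokines, growth factors and their receptors in MDA-MB-231, a human breast adenocarcinoma cell line that the labels give as negative for ER, PR and HER2. The series holds 1 group with 3 repeats, whose columns are named A, B and C, so no condition is compared with another. The array was made to look for candidate mediators of tumour angiogenesis, lymphangiogenesis and metastasis in normal breast and several breast cancer lines. The other samples are not analysed here. ER, PR and HER2 transcripts were not among the 178 targets. The Ct is the cycle at which a reaction crosses its detection level, so a lower Ct is a higher level. Levels are given as percent of ACTB (beta-actin) in the same repeat, as a geometric mean over the repeats, and their errors as SD in cycles, where 1 cycle is a 2-fold difference. ACTB itself had a mean Ct of 15.1 ± 0.13 (SD, n = 3). The labels do not say that the repeats were separate cultures, so SDs and limma p-values measure only the spread between these repeats, which may be technical. Permutation and binomial p-values take transcripts or single Ct values as units and do not measure that spread. Comparisons between transcripts assume that their primer pairs amplified with equal efficiency. All levels assume that each primer pair amplified only its own transcript, which was not tested here.

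Of the 178 target transcripts, 163 gave a Ct below 40 in all 3 repeats, among them 88 of 99 ligand and 74 of 78 receptor transcripts. The highest was CRLF1, a secreted partner of the cytokine CLCF1, at 116.5% of ACTB ± 0.21 cycles (SD, n = 3), the only target at or above 100%. The matricellular growth factor CTGF (current symbol CCN2) followed at 18.26% ± 0.37 cycles. FSHB, the beta subunit of follicle-stimulating hormone, stood at 14.03% ± 0.18 cycles. The growth factors TGFB2 and TGFB1 stood at 12.1% ± 0.54 cycles and 10.08% ± 0.48 cycles. Next came the LIF receptor LIFR at 8.737% ± 0.26 cycles and PRKAR1A, a regulatory subunit of protein kinase A whose row shares its primer name with PROK1, at 8.021% ± 0.16 cycles. PITPNM3, described as a receptor for CCL18, stood at 7.536% ± 0.11 cycles and the neurotrophin BDNF at 7.519% ± 0.45 cycles. The TNF receptor TNFRSF1A stood at 6.699% ± 0.16 cycles. CSF1, the macrophage growth factor, stood at 6.606% ± 0.33 cycles, and VEGFC, a lymphatic endothelial growth factor, at 6.47% ± 0.19 cycles. In all, 31 transcripts stood at or above 1% of ACTB, of which 17 were ligands and 13 receptors. At the other end, 46 ligands and 27 receptors stood below 0.01%.

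**Figure D1:**
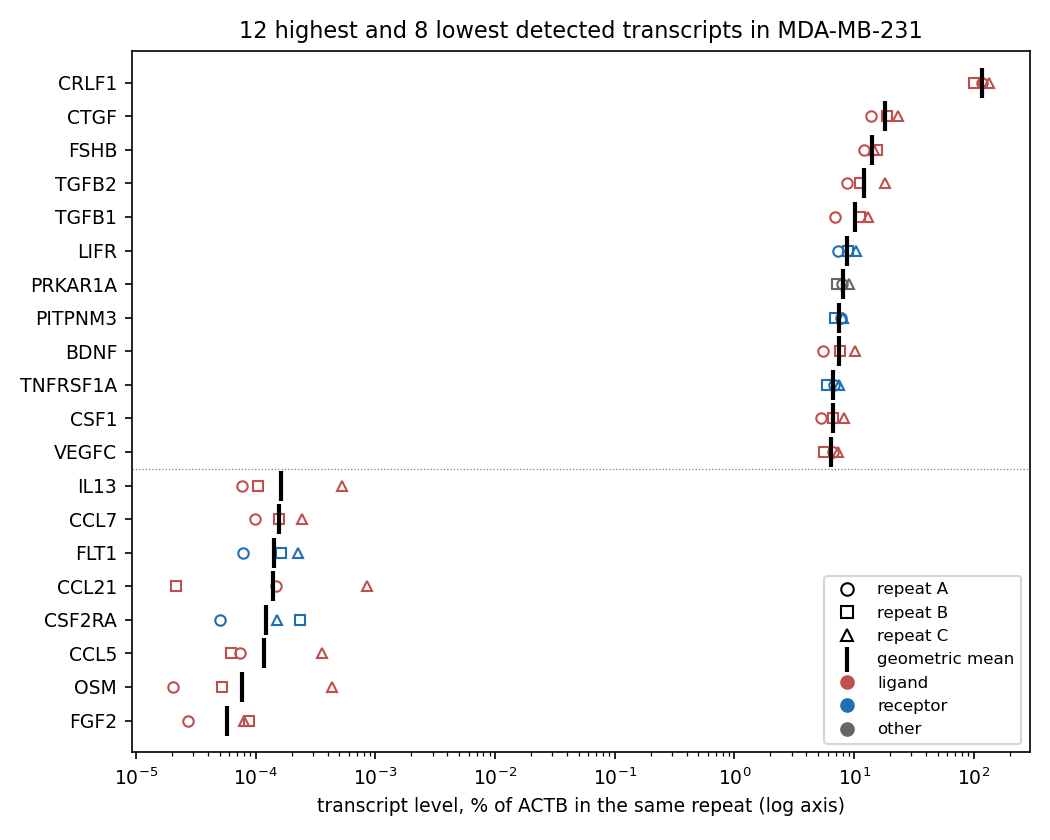
Levels of the 12 highest and 8 lowest detected transcripts in MDA-MB-231, as percent of ACTB in the same repeat on a log axis. Symbols are the 3 repeats, coloured by class, and black bars are geometric means, which run from 5.71e-05% for FGF2 to 116.5% for CRLF1.

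Detected levels spanned 2040000-fold from CRLF1 to FGF2. Without repeat C the lowest was OSM, at 3.246e-05% of ACTB against 4.852e-05% for FGF2, and without repeat A OSM stood at 0.0001507%. FGF2, a growth factor for fibroblasts and endothelium, stood at 5.71e-05% of ACTB ± 0.94 cycles (SD, n = 3) and the cytokine OSM at 7.711e-05% ± 2.27 cycles. The chemokines CCL5, CCL21 and CCL7 stood at 0.000118%, 0.000139% and 0.0001556%, with SDs of 1.40, 2.65 and 0.65 cycles, and the Ct of CCL7 in repeat A is exactly 35. CCL5 was 6.767e-05% without repeat C, and CCL21 5.631e-05% without C and 0.0003522% without B. The GM-CSF receptor CSF2RA stood at 0.000121% ± 1.15 cycles, the VEGF receptor FLT1 at 0.0001422% ± 0.78 cycles and IL13 at 0.0001615% ± 1.48 cycles. CSF2RA was 0.0001881% without repeat A and IL13 8.991e-05% without C. No Ct was listed in any repeat for 14 transcripts. They were the ligands CCL4, CCL8, CCL15, CCL22, GH2, IL19, IL33, PRL, TNFSF14 and WNT3 and the receptors FGFR2, FLT3, IL1RL1 and IL3R (current symbol IL3RA). Every other transcript had a Ct in all 3 repeats, even late ones such as OSM and CCL21. A missing Ct may thus not mean no signal by 40 cycles, and what it stands for was not tested. The FGFR2 and WNT3 rows carry primer names of FGFR1 and Wnt-3a. TNFSF11 (RANKL), an osteoclast differentiation factor, had Ct values of 37.97 and 38.37 in repeats A and B and 40 in repeat C, and was counted as not detected. The number detected depended on the Ct limit, and 102 transcripts remained with a limit of 30 cycles.

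Among the growth factor lists, the VEGF family ligands were spread widely. VEGFC stood at 6.47% of ACTB, VEGFA, the main endothelial growth factor, at 0.0429% ± 1.16 cycles (SD, n = 3), and VEGFD at 0.000509% ± 0.25 cycles. VEGFA differed between repeats, with 0.1084% in A against 0.02844% in B and 0.02563% in C. The 4 VEGF family receptors had a median of 0.00472% ± 0.53 cycles, from FLT1 at 0.000142% to KDR (VEGFR2) at 0.18%, and none reached 1%. The angiopoietin and Tie transcripts ANGPT1, ANGPT2 and TEK lay between 0.0223% and 0.185%, with a median of 0.088%. Of the 18 other growth factors and receptors measured, 17 were detected, with a median of 0.139% ± 0.18 cycles at percentile 92.1 of 10000 random lists of the same size. In this list 6 members stood at or above 1%, among them TGFB2, EGFR at 6.381% and TGFBR2 at 3.573%, and 6 stood below 0.01%, among them FGF2 and TGFBR1 at 0.00142% ± 2.02 cycles (0.000655% without repeat C and 0.002548% without B). With the undetected FGFR2 set to 40 cycles, the list's median was 0.0469%. The 5 lymphangiogenesis transcripts had a median of 0.000882% ± 0.82 cycles (percentile 3.18), from CCL21 at 0.000139% to VEGFC. The colony stimulating factor transcripts had a median of 0.0983% ± 0.18 cycles (percentile 75.3), from CSF2RA to CSF1.

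The 22 detected interleukins of 24 measured had a median of 0.00357% of ACTB ± 1.33 cycles (SD, n = 3), at percentile 2.99 of random lists. LIF, a cytokine of the IL6 family, stood at 4.715%, IL1B at 1.523% and the neutrophil chemoattractant CXCL8 at 1.506%, while 14 interleukins lay below 0.01%. The 19 detected interleukin receptors of 21 measured had a median of 0.153% ± 0.21 cycles, at percentile 95.8, with 4 at or above 1% and 5 below 0.01%. The 4 were LIFR, OSMR at 5.077%, IL7R at 1.342% and IL15RA at 1.212%. Set to 40 cycles, the undetected IL1RL1 and IL3R brought the receptor median to 0.0466%. The 14 detected CC chemokines of 18 measured had a median of 0.000858% ± 1.04 cycles, at percentile 0.09, and 12 lay below 0.01%. CCL28, a mucosal chemokine, was the highest of them at 1.048%. With the 4 undetected CC chemokines set to 40 cycles, the median was 0.000289%. The 14 CXC, CX3C and XC chemokines had a median of 0.00814% ± 0.45 cycles (percentile 25.4), and the 15 chemokine receptors, all detected, a median of 0.0122% ± 0.31 cycles (percentile 38.9). CXCR5, the receptor of the B-cell chemokine CXCL13, was the highest of these 15 at 1.867% ± 0.90 cycles.

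In the TNF superfamily, 6 of 8 ligands were detected, with a median of 0.039% of ACTB ± 0.28 cycles (SD, n = 3, percentile 63.9) and none at or above 1%. TNFSF18 (GITR ligand) was the highest at 0.6739% ± 0.21 cycles and TNF the lowest at 0.001819% ± 2.38 cycles, or 0.0007193% without repeat C and 0.003493% without A. The ligand median was 0.0201% without repeat C and 0.0157% with the undetected TNFSF11 and TNFSF14 set to 40 cycles. All 10 TNF superfamily receptors were detected, with a median of 0.0453% ± 0.17 cycles (percentile 71.6), and TNFRSF1A and LTBR, at 6.699% and 3.794%, exceeded 1%. Of the interferon list, IFNG stood at 0.000313% ± 1.95 cycles (0.0001491% without repeat C and 0.0005566% without A) and its receptor IFNGR1 at 1.534%. None of the Toll-like receptor pathway transcripts was measured. Of the cell type markers, the endothelial KDR and TEK stood at 0.18% and 0.0223%, the lymphatic endothelial FLT4 (VEGFR3) at 0.000882% and the myeloid CSF1R at 0.0383%. Lymphoid, epithelial and mesenchymal markers of the fixed lists were not measured.

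The array pairs ligands with their receptors, and each pair was compared within each repeat. Among the VEGF pairs, VEGFC exceeded its receptor FLT4 by 12.84 ± 0.44 log2 (SE, n = 3), or 7332-fold (95% interval 3252 to 16530), with a limma adjusted p of 8.15e-05. VEGFC also stood 256-fold above NRP2 and 36-fold above KDR. VEGFA stood 301.6-fold above FLT1 but KDR stood 4.189-fold above VEGFA (limma adjusted p = 0.02274, 0.1466 without repeat B), a call also lost without variance moderation. KDR stood 353-fold above VEGFD, and VEGFD and FLT4 did not differ past the threshold (limma adjusted p = 0.138). The VEGFA to FLT1 difference was 8.24 log2 and 7.14 without repeat A, and the VEGFA to KDR difference −2.07 and −2.75. OSMR exceeded its ligand OSM by the largest margin of the 59 tested pairs fixed beforehand, 65840-fold (interval 11770 to 368200), with a limma adjusted p of 0.0001641. IFNGR1 stood 4894-fold above IFNG, TNFRSF1A 3683-fold above TNF and IGF1R 2165-fold above IGF1, each in 3 of 3 repeats. The Ct of IFNG in repeat A and of IGF1 in repeat C is exactly 35. TGFB1 stood 7099-fold (interval 1647 to 30600) above TGFBR1, with a limma adjusted p of 0.0001701, and 2.822-fold above TGFBR2 (limma adjusted p = 0.01793, 0.1154 without repeat B). CSF2 (GM-CSF) stood 2086-fold above CSF2RA and CXCL8 stood 1603-fold above CXCR1 and 1053-fold above CXCR2. CXCR5 stood 1644-fold above CXCL13. EGFR stood 45.99-fold above EGF, CSF1 172.4-fold above CSF1R and IL6 13.21-fold above IL6R.

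Of 66 pairs fixed beforehand and present on the array, 59 had both members detected, and limma called 50 of them different at an adjusted p of 0.05. The ligand was higher in 23 and the receptor in 27. Detected levels spanned 2040000-fold against a median SD of 0.451 cycles, so pairs of unrelated transcripts may often be called as well. Unmatched pairs were not tested, so the count shows nothing particular to ligands and their receptors. Neither the p-values nor the intervals cover unequal primer efficiency. At a Ct limit of 35 only 48 pairs could be tested, with the ligand higher in 21 and the receptor in 19. The 11 pairs left out had all been called, among them those of OSM, IFNG, IGF1, CSF2 and CCL5, and VEGFA with FLT1. In 8 CC chemokine pairs the receptor was higher in 7, and CCL20 over CCR6 was the exception at 9.514-fold. The 7 became 6 without variance moderation, as the call for CCL11 and CCR3 was lost. At a Ct limit of 35 only 3 of the 8 pairs remained, 2 with the receptor higher. CCL5 is the ligand in several of the 8 pairs. With 1 pair per ligand and receptor 5 were left, 4 with the receptor higher. Of 17 interleukin pairs the receptor was higher in 9 (8 without repeat B and 10 without C) and the ligand in 6. Of 14 CXC, CX3C and XC chemokine pairs the ligand was higher in 7 and the receptor in 3, and the CXCL8 pairs are counted here and among the interleukins. These 7 include CXCL10 and CXCL11 over CXCR3, which have identical Ct values, and fall to 5 without repeat B, without repeat C or without variance moderation. Both had a limma adjusted p of 0.04317, which became 0.1819 without B and 0.1116 without C. The 14 pairs share members. With 1 pair per ligand and receptor, kept in listed order, 8 of them were left, 3 with the ligand and 3 with the receptor higher. That order kept CXCL9 with CXCR3 (receptor higher) and dropped CXCL10 with CXCR3 (ligand higher). The even split depends on that order. Of 4 TNF superfamily pairs the receptor was higher in 3. TNFRSF13C over TNFSF13B, 1 of these, was lost without repeat A, without repeat B and without moderation, with limma adjusted p-values of 0.1426 without A and 0.1819 without B. With the textbook pairs added later, 9 TNF superfamily pairs were tested, 3 with the ligand and 3 with the receptor higher. CXCL12 and its receptor CXCR4, which guides metastatic homing, differed by −0.19 log2 with a limma adjusted p of 0.6536 and a fold interval of 0.5683 to 2.279. LIF and LIFR (limma adjusted p = 0.06085) and KITLG and KIT (limma adjusted p = 0.1399) did not pass either. LIFR over LIF, at −0.89 log2, did pass at a Ct limit of 35, with undetected members at 40 cycles and without variance moderation. The LIF and LIFR values are the same in these settings, so the passes are not separate support. With undetected members at 40 cycles, for example, the SE was 0.22 against 0.34 in the main test. The KITLG to KIT difference was 2.85 log2, and 5.07 without repeat C, where it passed. For 6 pairs with 1 member undetected, only bounds can be given, taking 40 cycles as the floor where no Ct was listed and the Ct given above for TNFSF11. Where no Ct was listed, the folds that follow are bounds only if a missing Ct means no signal by 40 cycles. LTBR stood at least 1190000-fold above TNFSF14, CCR2 at least 10200-fold above CCL8, TNFRSF11A (RANK) at least 9720-fold above TNFSF11 and CCR5 at least 9430-fold above CCL4. CCR4 stood at least 1300-fold above CCL22. Without repeat C both Ct values of TNFSF11 lie below 40, so the 6230-fold for TNFRSF11A there is an estimate and not a bound. The bound for IL3 above IL3R was 342-fold with an SD of IL3 of 2.30 cycles, and 174-fold without repeat C and 773-fold without B. Tested against a 10-fold difference, limma called 28 pairs, 11 with the ligand and 17 with the receptor higher. Leaving out a repeat gave 49 calls without A, 43 without B and 52 without C. Without repeat C the OSM difference moved from −16.01 to −17.23 log2 and the TNF difference from −11.85 to −13.11, and without repeat A they were −15.02 and −10.90. The IFNG difference of −12.26 became −11.43 without A and −13.24 without C, the TGFB1 to TGFBR1 difference of 12.79 became 11.87 without B and 13.72 without C, and the IGF1 difference of −11.08 became −11.84 without A.

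**Figure D2:**
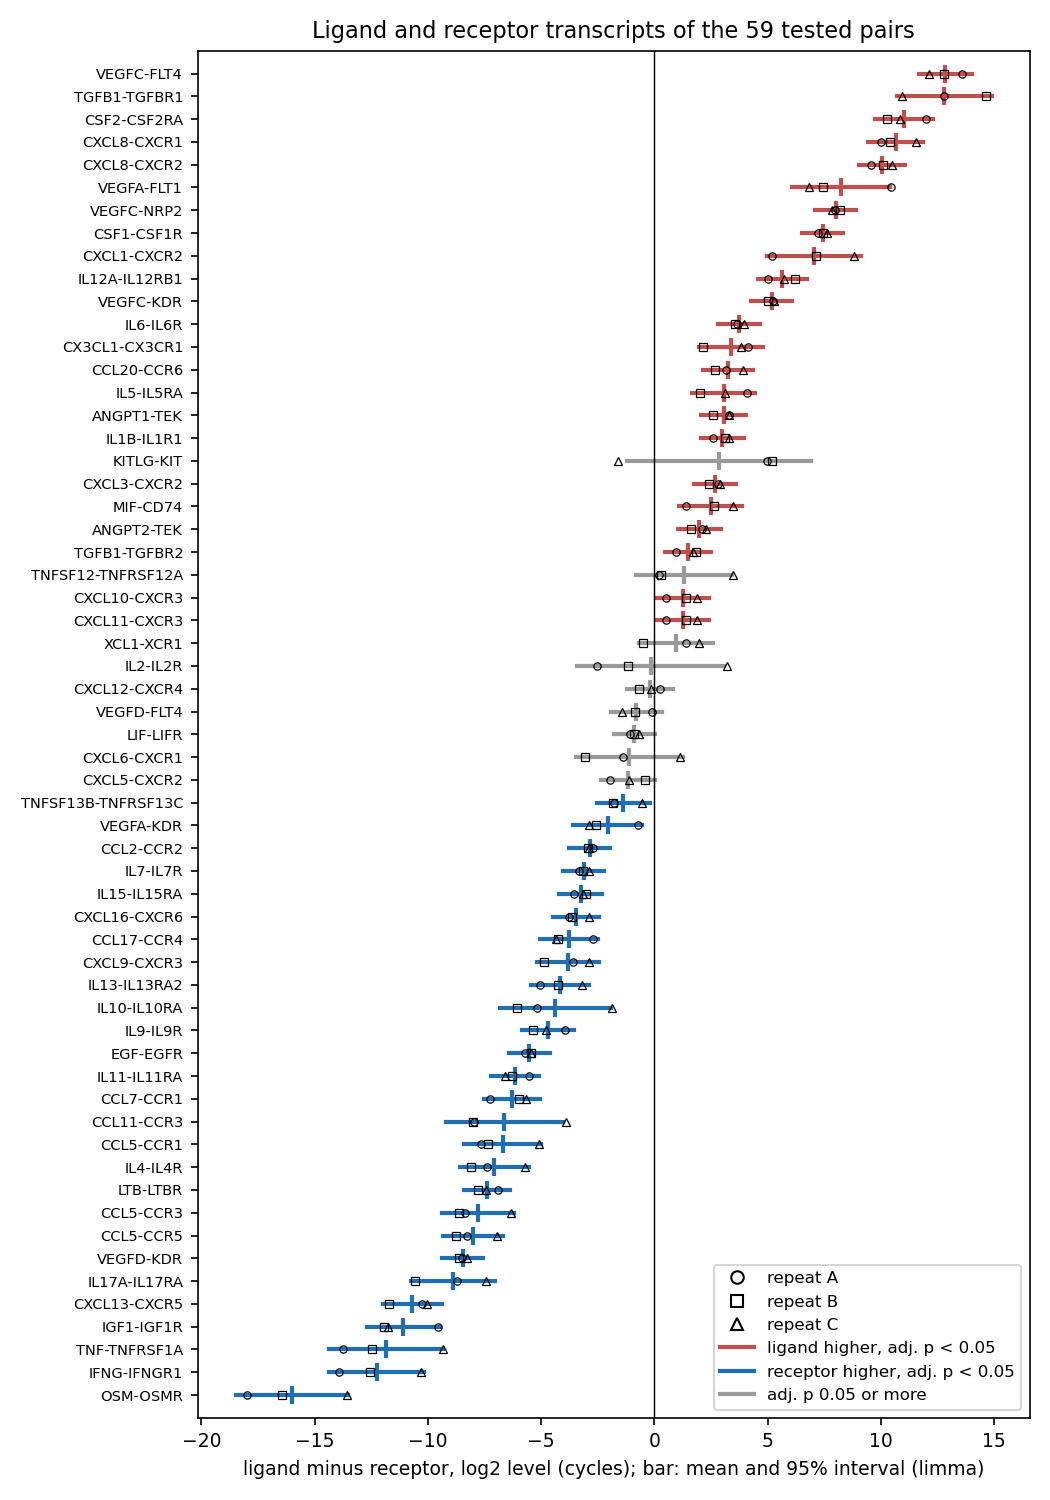
Ligand minus receptor log2 level for the 59 tested pairs, with the mean and 95% interval from limma as coloured bars and the 3 repeats as open symbols. Red marks the 23 pairs with the ligand higher, blue the 27 with the receptor higher and grey the 9 that did not pass.

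Over the array as a whole, the 88 detected ligand transcripts had a median of 0.00752% of ACTB and the 74 detected receptor transcripts a median of 0.0293%. The difference of −1.96 log2, or 3.9-fold, did not pass a two-sided permutation test over transcripts (100000 resamples, p = 0.0651), and transcripts are not independent replicates. The direction was the same in each repeat, with differences of −2.07 in A, −2.10 in B and −1.65 in C. The repeats measure the same transcripts, so this agreement is no separate support. Means in place of medians gave a smaller difference of −1.32 log2, or 2.49-fold (permutation p = 0.0809). With undetected transcripts set to 40 cycles the difference of medians was −2.81 log2, or 7.03-fold, and passed the test (permutation p = 0.00511). That setting assumes that a missing Ct means no signal by 40 cycles.

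The median spread between repeats was larger for late transcripts. The median SD was 0.267 cycles for the 60 transcripts with a mean Ct under 25 and 1.09 cycles for the 51 with a mean Ct of 30 or more. Of the 38 transcripts with an SD above 1 cycle, 34 were ligands and 4 receptors. The largest SDs were those of INHBB, a subunit of activin and inhibin (4.35 cycles, Ct 22.11, 21.98 and 29.79 in A, B and C), and KITLG, the ligand of KIT (3.92 cycles, Ct 25.3, 25.46 and 32.39). IL16 had an SD of 3.34 cycles (Ct 25.58, 31.25 and 31.6), BMP2 of 2.87 cycles (32.97, 32.58 and 28.03) and IL2 of 2.86 cycles (33.09, 33.42 and 28.53). In raw cycles, 75 of 88 detected ligands were higher in repeat C than in the mean of A and B, with a median shift of 0.562 cycles, against −0.463 for repeat A and −0.287 for B, each set against the mean of the other repeats. For the 41 ligands with a mean Ct under 28 repeat A stood furthest out, with −0.44 against −0.005 for B and 0.295 for C. Of the 74 receptors 41 were higher in repeat C, with a median shift of 0.0375 cycles, and ACTB shifted by −0.215 in that repeat. Among 47 ligands with a mean Ct of 28 or more, 42 were higher in repeat C, with a median shift of 1.46 cycles. On raw cycles BMP2 stood 26.8-fold, IL2 26.4-fold, TNF 13.9-fold and HGF 7.29-fold higher in repeat C. The file gives IL2 and IL2R (current symbol IL2RA) the same primer name.

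**Figure D3:**
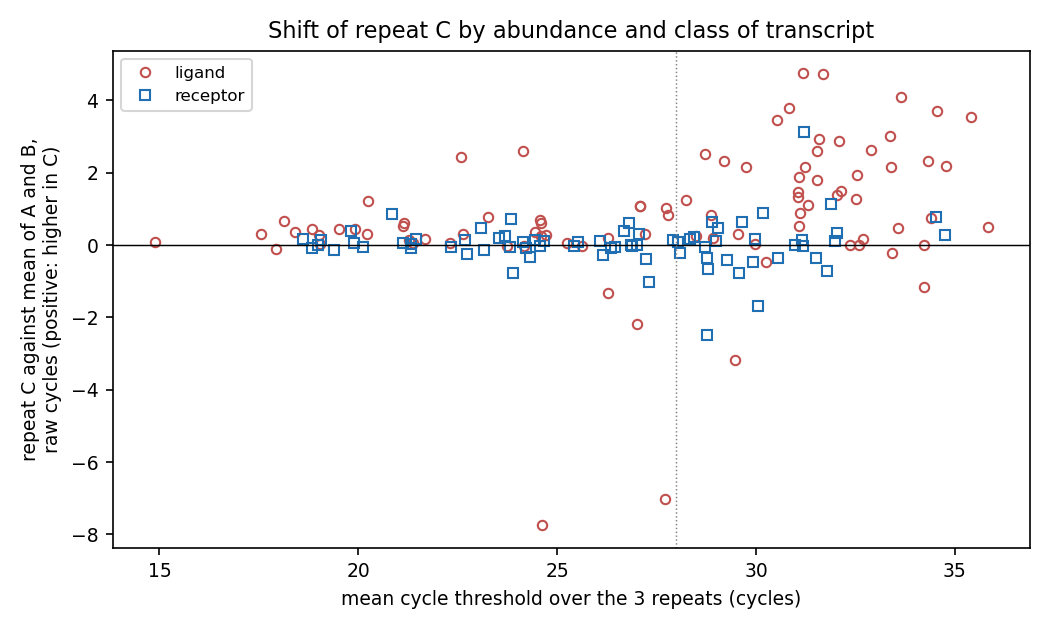
Shift of repeat C against the mean of repeats A and B in raw cycles (positive is higher in C), plotted against mean Ct, with ligands as red circles and receptors as blue squares. The dotted line at 28 cycles marks the late transcripts, where 42 of 47 ligands and 17 of 30 receptors lie above 0.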

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

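The settings that left out values of exactly 35 cycles or rows of doubtful identity, added pairs, left out a repeat for added pairs or bounds, or kept 1 pair per ligand and receptor were chosen after seeing the data, and the other settings before. The 163 detected transcripts became 102 at a limit of 30 cycles, and were 150 at 35, 164 with detection in at least 1 repeat and 157 without values of exactly 35. The number at or above 1% of ACTB was 30 or 31 under all alternatives run. The 50 limma calls became 28 against a 10-fold difference (11 ligand, 17 receptor) and 77 with pairs added (36 and 41), since more pairs were tested. Keeping 1 pair per ligand and receptor gave 38 calls, 15 with the ligand higher, from 44 pairs. There were 44 calls without variance moderation (CCL11, IL10, MIF, VEGFA to KDR, TNFSF13B, CXCL10 and CXCL11 lost) and 40 of 48 pairs at 35 cycles (11 called pairs untested). With undetected members at 40 cycles 57 of 66 were called, and 49 of 57 without the doubtful rows CXCL11, IL2R and PROK1. CXCL10, with the same Ct values as CXCL11, stayed in and was still called. An amplification factor of 1.9 for every assay scales each difference and its error alike, so its 50 calls were fixed and say nothing of unequal primers. The difference is taken within each repeat, which acts as the block, and with no replicate block there were 51 calls. Leaving out a repeat gave 43 to 52 calls, 19 to 23 with the ligand and 24 to 30 with the receptor higher. Without repeat B the calls for IL10, MIF, VEGFA to KDR, TGFB1 to TGFBR2, TNFSF13B, CXCL10 and CXCL11 were lost, TNFSF13B also without A, and CXCL10 and CXCL11 also without C and with pairs added. Without repeat C the calls for KITLG, CXCL6 and IL2 were gained, where limma gave all pairs 1 common variance. LIF to LIFR was gained at 35 cycles, with undetected members at 40 cycles and without moderation, and CXCL5 to CXCR2 with no block. The uncalled CXCL12 to CXCR4 difference turned to 0.05 log2 without repeat B (range −0.40 to 0.05), and the uncalled IL2 to IL2R difference to 1.02 without A and 0.34 without B, against −1.86 without C. For the 25 transcripts named by rule for their level or SD, 12 of 75 levels under another reference, another factor or the deposited percentages moved by more than the SD over repeats. These, in 11 transcripts, moved at an amplification factor of 1.9 (FGF2 to 0.0001654%, FSHB to 16.23%) or, for PITPNM3, also with the deposited percentages (8.152%). Leaving out 1 of 3 repeats cannot move a mean by 1 SD, so those levels are not counted here. Of 621 alternative values for single pairs, the factor of 1.9 left out, 570 kept their direction and side of the threshold, 41 lost the call and 7 gained it. Ligands against receptors gave −2.81 log2 with undetected transcripts at 40 cycles, past the threshold. The difference was −1.32 log2 with means for medians and −2.12 to −1.87 without a repeat, not past it. With undetected transcripts at 40 cycles the list medians were 0.0469% of ACTB for other growth factors and receptors, 0.0466% for interleukin receptors, 0.000289% for chemokines CC and 0.0157% for TNF superfamily ligands, whose range without a repeat was 0.0201% to 0.0434%. Otherwise the cause was not tested. Late Ct values limit the low transcripts, since the median SD was highest, at 1.09 cycles, for a mean Ct of 30 or more.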

Other observations

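Another 39 textbook pairs on the array, chosen after the values were seen, were tested with limma together with the fixed pairs. The ligand was higher in 15, the receptor in 14, and 10 did not pass. Leaving out a repeat gave 27 calls without A, 26 without B and 35 without C. CRLF1 and its partner CLCF1 bind the CNTF receptor, and CRLF1 stood 21620-fold (95% interval 10470 to 44650) and CLCF1 533.7-fold above CNTFR, with limma adjusted p-values of 5.044e-05 and 5.328e-05. FSHB stood 3191-fold (interval 1526 to 6675) above the FSH receptor FSHR. PDGFC stood 1141-fold above PDGFRA (697-fold without repeat C), and BDNF stood 984.6-fold above NGFR and 589.5-fold above its receptor NTRK2. TNFSF18 stood 195.4-fold above TNFRSF18 and CCL28 stood 40.69-fold above CCR3. EDN1, the vasoconstrictor endothelin 1, stood at 1.389% of ACTB and 8.34-fold above EDNRA, while EDNRA stood 21.06-fold above EDN2 (40.64-fold without repeat C).

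Receptors led in other added pairs. LIFR stood 113300-fold above OSM (247100-fold without repeat C and 63520-fold without A) and PITPNM3 stood 27240-fold above CCL18. The bone morphogenetic protein receptor BMPR2 stood 2170-fold (interval 291.6 to 16150) above BMP2, and 6562-fold without repeat C, 1148-fold without A and 1356-fold without B. The receptor NOTCH (described in the file as Notch 1) stood 94.57-fold above its ligand DLL4. INHBA and the activin receptor ACVR1B did not differ past the threshold (limma adjusted p = 0.05834). INHBB against ACVR1B differed by −1.10 log2 with a fold interval of 0.08745 to 52.3, and by 1.55 log2 in the other direction without repeat C (limma adjusted p = 0.01403), where limma gave all pairs 1 common variance.

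All tests in the 3 patterns that follow were chosen after the results were seen, and with 1 group no biological explanation was tested. Ligand transcripts were higher in repeat C, and more cDNA in that repeat is argued against, since ligands shifted 0.525 cycles more than receptors (permutation p = 1e-05, the smallest the resamples can give) and ACTB moved the other way. Scatter of late reactions would split evenly, but 42 of 47 late ligands were higher (exact binomial p = 2.46e-08), and late receptors shifted less (difference 1.37 cycles, permutation p = 0.00141). Late ligands and late receptors were not matched on Ct, and late ligands shifted 1.17 cycles more than early ones. A part of the 1.37 cycles that goes with lateness thus cannot be told apart. For an equal background in every ligand assay of repeat C, 9 of the 47 late ligands stood in C below 0.000481% of mean ACTB. The median amount added to late ligands was 0.000962%. That gap is within the spread of late reactions (median SD 1.09 cycles at a mean Ct of 30 or more), so the count cannot decide. For ligands with a mean Ct under 28, repeat A stood further out (−0.44 cycles) than repeat C (0.295). For late ligands an equal background in repeat C stays open. So does a difference in how ligand assays were run between repeats, not in C alone, or in the cells.

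CXCL10 and CXCL11 have the same Ct in all 3 repeats, 27.79, 27.08 and 26.36. Among 13530 pairs of transcripts this was the 1 pair identical in every repeat, no pair matched in exactly 2, and chance gives an expected 0.00012 full matches. Whether 1 measurement was entered for both transcripts stays open, since the match is what raised the question and so decides nothing. The criterion of this test was rewritten after its result was seen, to ask for a shared primer name, and the names of the 2 rows differ.

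A Ct of exactly 35 occurs 7 times, in 6 ligand transcripts (CCL11, CCL7, CXCL14, IFNG, IL31 and IGF1), 5 of them in repeat A. Chance rounding is argued against, since 8 of 53 single values from 33 to under 40 are whole numbers (exact one-sided binomial p = 5.94e-08). Under 33 cycles 3 of 438 are. Of the 8, 7 are the values of 35 that raised the question. A limit of 35 set for every late reaction is argued against too, since 15 values above 35 remain. A limit or a substituted value used for some reactions stays open and was not tested.

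IL20 had Ct values of 24.09, 28.48 and 28.46 and the Wnt receptor FZD1 had 26.64, 29.25 and 30.42 in repeats A, B and C. IL2 and IL2R carry the same primer name in the file, as do PROK1 and PRKAR1A. The primer names of the FGFR2 and WNT3 rows are those of FGFR1 and Wnt-3a.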
